A study of Homo sapiens with 19 samples.

How the data were processed

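GRHL2 ChIP-seq was measured in 18 libraries of MCF7 cells: 3 lines (wild type and 2 S118A knock-in lines), with E2 or vehicle, and 3 libraries per group. Cells were fixed for 10 min with 1.5% formaldehyde and sequenced as paired 150 bp reads, per the labels. The submitters' processing notes name FastQC, cutadapt, Trim Galore, Bowtie2, MACS2 and deepTools with build hg38, with no versions, roles or thresholds. The authors deposited 1 peak list per library, with peak start and end in bp (start counted from 0) and an integer peak score as the caller wrote it. The deposited score is of at least 20 in each list, and what it is relative to is not stated. Whether the input sample served as the control of the peak calls is not stated either, and no list of that sample was used. The lists give no read counts, so depth is unknown and no interval or lower limit that needs depth is given.

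Groups came from the sample titles. Peaks on chromosomes 1 to 22 and X were kept (0 to 3 peaks per library lay on other sequences) and merged into regions where they shared at least 1 bp. A library calls a region when 1 of its peaks overlaps it. Scores were not compared between lists. No pair of the 153 pairs of libraries had identical lists. Genes were the 19970 protein-coding genes of the RefSeq gene table supplied for the same assembly. That table gives gene spans without strand, so distances run to the gene span, not to the transcription start as planned, and exons and introns were not separated. Sequence under the regions was not analysed here, so the planned motif test was not run.

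Tests, gene lists and alternatives were fixed before the data were examined, unless said otherwise. Peak numbers, shares of regions and regions per gene were compared by exact two-sided permutation tests. Labels of E2 and vehicle were permuted within lines (8000 arrangements), and line labels within treatments. Each region called by 3 to 15 libraries was tested by an exact stratified test of called against not called, with Benjamini-Hochberg adjustment and a threshold of 0.05. Regions of S118A had in addition to lie on the same side of wild type in both lines. The 7 gene lists hold 171 genes, of which 6 are in more than 1 list, and use regions within 50 kb of a gene. Lists among changed regions were set against 10000 random lists of genes with as many tested regions. Genes named for a comparison were the first 15 with a higher and the first 10 with a lower share of calling libraries, 1 region per gene, within 50 kb. Places left by a lack of passing regions were filled from regions that missed the threshold. The 10 genes GREB1, TFF1, PGR, XBP1, ESR1, FOXA1, GATA3, GRHL2, CDH1 and CLDN4 were named whatever their values.

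After the data were seen, a rank analysis was added. Over the 11437 regions called by all libraries, the highest peak score of each region was ranked within each library, with ties sharing their mean rank (at most 9337 more regions than distinct scores in a library). Ranks were turned into normal scores and fitted with limma (empirical Bayes, 6 group means, 12 residual degrees of freedom). Its named regions follow the same numbers, ordered by p. Gene lists were tested by camera with an estimated correlation, and with a preset correlation of 0.01 as the alternative, and the response over a set by fry. Lists against the share of all regions, the adjusted values of the 10 fixed genes, each S118A line at ESR1, the flanks of ESR1 and chromosome gene density were added at the same stage.

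The alternatives were a list without its weakest 25%, lists cut to the shortest (15639 peaks), an overlap of at least 0.5 of a peak or region, all sequences, base pairs covered, and no filter or a filter of 6 to 12 calling libraries. Others were Fisher's test without strata, 2 of 3 libraries for a gained region, distances of 10 and 100 kb, a replicate block, and each library left out. The regional test was tested on simulated data. With 200 of 10948 regions called by 100% of 1 arm and 0% of the other it recovered 100%; at 95% and 5% it recovered 40.5% for E2 and 57% for S118A, and at 80% and 20% it recovered 0%. The rank fit, with 200 shifted regions, recovered 69.5% of E2 shifts of 0.5 and 90% of shifts of 1, with 3.47% and 3.74% of its calls false. At a shift of 1.5 up to 12.8% of its calls were false. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.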

Results

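GRHL2 binding was mapped by ChIP-seq, which sequences the DNA bound by a protein, in MCF7 cells. MCF7 is an established breast cancer cell line that carries the estrogen receptor ER, and GRHL2 is a transcription factor of epithelial cells. The lines were wild-type MCF7 and 2 S118A knock-in lines, called S118A line 1 and S118A line 2 here. In these lines the serine of ER that S118A names, a known phosphorylation site, is replaced by alanine. Cells kept for 3 days in estrogen-stripped medium received 10 nM 17β-estradiol (E2) or vehicle (0.1% ethanol) for 30 min. Each of the 6 groups had 3 GRHL2 libraries, 18 in all, and 1 input sample had no list in the comparisons. Each library came as a list of peaks on build hg38. The lists hold no read counts, so the read depth behind a peak is unknown, and a region that is not called is not shown to be unbound. Nothing states that replicates are separate cultures, so the p-values measure only the spread between these samples.

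The libraries held 15639 to 20985 GRHL2 peaks on chromosomes 1 to 22 and X, with a mean of 19083 ± 1684 (SD, n = 18). Merging overlapping peaks gave 31730 regions, of which 11437 were called by all 18 libraries. Of all regions, 58.0% overlapped the span of a protein-coding gene. A gene end lay within 1 kb of 16.5% of the regions, against 4.13% after the regions were moved by 1 Mb. Libraries of the same line and treatment shared a mean of 0.753 of their combined regions (Jaccard index, 18 pairs). The mean was 0.745 for the same line under the other treatment and 0.723 for another line under the same treatment.

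**Figure D1:**
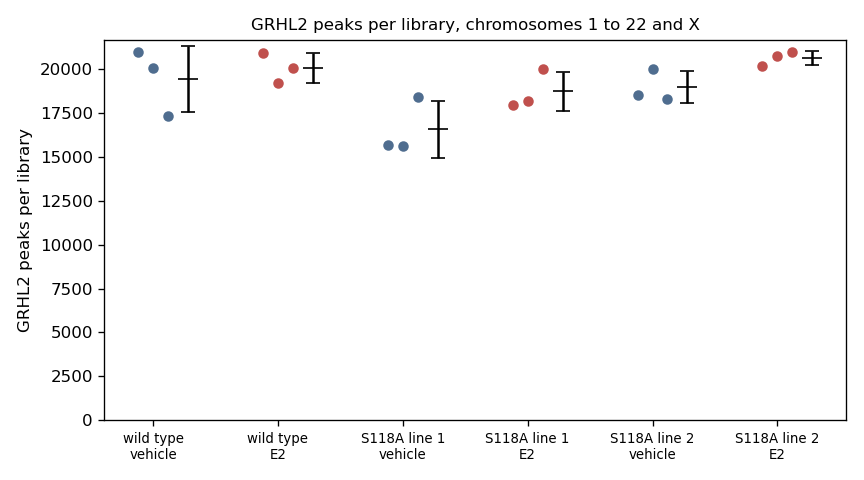
GRHL2 peaks per library on chromosomes 1 to 22 and X (y axis, number of peaks) in the 6 groups (x axis). Dots are libraries and bars are the mean ± SD (n = 3); S118A line 1 with vehicle has the lowest mean, 16580 peaks, and S118A line 2 with E2 the highest, 20652 peaks.

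The E2 comparison asks how 30 min of estrogen changed GRHL2 binding. Regions near estrogen-induced genes were called more often with E2, and GRHL2 peak lists were longer. Of the 164 regions within 50 kb of the 37 estrogen-induced genes, E2 libraries called 64.7% ± 6.5 (SD, n = 9) and vehicle libraries 54.8% ± 6.6 (SD, n = 9). Near GREB1, an early estrogen target, E2 libraries called 6.56 ± 1.59 of 11 regions and vehicle libraries 4.67 ± 0.87 (SD, n = 9 each). The mean number of peaks was 19826 ± 1114 (SD, n = 9) with E2 and 18341 ± 1882 (SD, n = 9) with vehicle.

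The rise of 1485 peaks with E2 had an exact p = 0.0223 (two-sided permutation within lines, 8000 arrangements). Without wild-type vehicle replicate 3, the shortest wild-type list, the rise was 1131 peaks with an exact p = 0.0572. Wild-type libraries averaged 20078 ± 839 peaks with E2 and 19463 ± 1898 with vehicle (SD, n = 3 each). S118A line 1 averaged 18748 ± 1113 and 16580 ± 1605, and S118A line 2 averaged 20652 ± 393 and 18980 ± 917. With 3 libraries against 3, a single line cannot go below an exact p of 0.1, and the lines gave 0.9, 0.3 and 0.1 in that order. The response of the S118A lines exceeded that of wild type by 1305 peaks (exact permutation p = 0.382). Without wild-type vehicle replicate 3 that difference was 2368 peaks with an exact p = 0.0198, so this library decides the call.

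The estrogen-induced list rose by 9.89 percentage points with E2, with an exact permutation p = 0.00075 and an adjusted p of 0.0158 over 21 list comparisons. The immediate-early list, genes switched on within minutes of a stimulus, rose from 52.2% ± 8.5 to 61.5% ± 4.1 of its 96 regions (SD, n = 9 each; adjusted exact p = 0.021). The epithelial junction and identity list rose from 62.2% ± 5.3 to 68.6% ± 2.7 of its 223 regions (SD, n = 9 each; adjusted exact p = 0.021). With lists cut to equal length its rise was 2.07 points with an exact p = 0.057. The estrogen-repressed list stood at 80.0% with E2 and 73.5% with vehicle (adjusted exact permutation p = 0.0639), and the list of luminal transcription factors and ER cofactors at 67.7% and 63.2% (adjusted exact permutation p = 0.137). The mesenchymal list stood at 58.1% and 56.3%, and the list of other cell types at 55.6% and 54.2%, with adjusted exact permutation p of 0.827 and 0.846.

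The share of all regions called was 4.70 points higher with E2 (exact permutation p = 0.0223), so the lists were also measured against it, a comparison chosen after the data were seen. The estrogen-induced list rose by 5.19 points beyond all regions and the immediate-early list by 4.56 points, each with an adjusted exact permutation p of 0.0315. The epithelial list stood 1.68 points beyond all regions (adjusted exact permutation p = 0.110). No list passed the test of a different E2 response in the S118A lines than in wild type. The largest difference was 10.8 points, for the list of other cell types (exact permutation p = 0.0623, adjusted p = 0.145). Leaving out 1 library gave 8.50 to 14.1 points, and an unadjusted exact p of at most 0.05 in 6 of 18 cases. Those were without E2 replicate 1 or vehicle replicate 3 of wild type or of S118A line 1, or E2 replicate 3 or vehicle replicate 2 of S118A line 2. For the estrogen-induced list the S118A response was -1.93 points relative to wild type (exact permutation p = 0.831). Measured against all regions these differences were 6.70 points for other cell types (exact permutation p = 0.108) and -6.01 points for the estrogen-induced list (exact permutation p = 0.165), and no list passed.

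**Figure D2:**
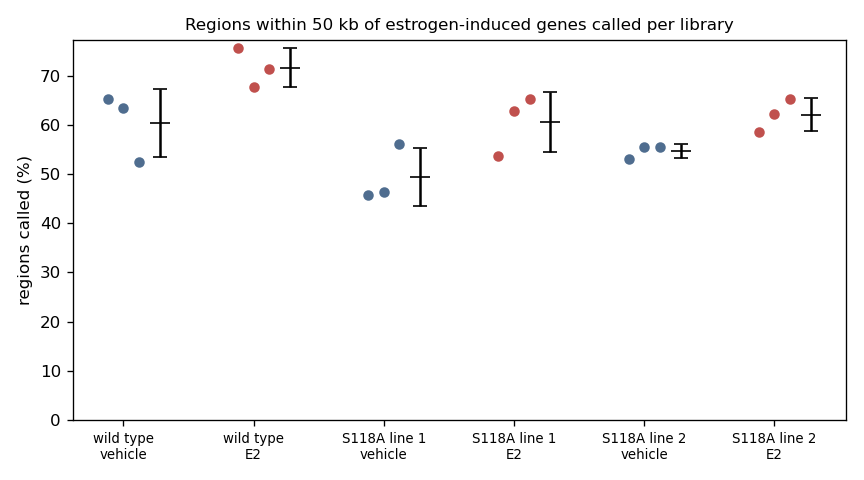
Percent of the 164 regions within 50 kb of estrogen-induced genes called as a GRHL2 peak by each library (y axis) in the 6 groups (x axis). Dots are libraries and bars are the mean ± SD (n = 3); over the 3 lines the mean was 64.7% with E2 and 54.8% with vehicle.

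Among 10 genes fixed in advance, GREB1 was the gene whose rise in called regions with E2 passed (exact permutation p = 0.0065, adjusted p = 0.0433 over 20 tests). The counts per gene were not set against the rise of all regions with E2. ESR1, which encodes ER, had 7.44 ± 3.17 called regions with E2 and 5.67 ± 2.78 with vehicle (SD, n = 9 each; adjusted exact p = 0.1). The means with E2 and vehicle were 2 and 1.67 for TFF1, 2.56 and 2.44 for PGR, 2.78 and 2.33 for XBP1, and 1.67 and 1.22 for FOXA1. They were 3.78 and 2.67 for GATA3, 7.33 and 7.44 for GRHL2 itself, 5.11 and 5.11 for CDH1, and 8.11 and 7.33 for CLDN4. None of these 8 genes passed the adjusted threshold.

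No single region passed the adjusted threshold for E2 in the exact stratified test of 10948 regions. At an unadjusted p of at most 0.05, 246 regions were called more often and 17 less often with E2. With lists of equal length the split was 104 and 49, so part of the imbalance moved with list length. With 1 library left out, 262 to 399 regions were called more often and 20 to 40 less often. The first count rose by over 1.5 times without wild-type vehicle replicate 1 (399), wild-type E2 replicate 2 (379), S118A line 1 E2 replicate 1 (377) or S118A line 2 vehicle replicate 2 (385). The second did so, to 27 to 40, without each library except vehicle replicate 1 and E2 replicate 2 of wild type, E2 replicate 2 and vehicle replicate 3 of S118A line 1, and E2 replicate 1 of S118A line 2. The smallest p the test can give, 0.00025, would have had to occur in 55 regions to pass. It occurred in 5 regions, each called by 9 of 9 E2 and 0 of 9 vehicle libraries, with an adjusted p of 0.547. They lay near GPAT3, an enzyme of glycerolipid synthesis (chromosome 4, 83651366 to 83651944), near TBX4 and inside OXR1, MIDEAS and CDYL. The next regions, which also missed the threshold, lay inside LRG1, KYNU, MAGI1, IMMP2L, ADARB2, PLEKHA7, ARHGEF33 and VXN and near RHOBTB1 and ADCY9. MAGI1 and PLEKHA7 are proteins of epithelial junctions, and ADCY9 is on the estrogen-induced list. JUP, of the epithelial junction and identity list, went the other way, with its region called by 0 of 9 E2 and 6 of 9 vehicle libraries. Regions called more often with vehicle, all with an adjusted p of 1, lay inside MCM4, ZNF407, JUP, DNAH5, MYO1B, PPP3CC, TMC1 and MCC and near CENPU and SPINK8. At an unadjusted p of at most 0.01, no list passed the adjusted threshold for more or fewer changed regions near its genes than random gene lists. The smallest adjusted p over lists and directions was 0.168, for 6 regions less often called in S118A near ESR1 and NCOA3.

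Counted by line, 168 regions were called by 3 of 3 E2 and 0 of 3 vehicle libraries of wild type, and 58 the other way round. S118A line 1 had 278 and 30 such regions, and S118A line 2 had 220 and 39. With equal list lengths the gained regions numbered 96, 100 and 77, and the lost regions of S118A line 1 numbered 96. The 168 gained regions of wild type were then looked up in the S118A lines, which had no part in choosing them. S118A libraries called 45.2% ± 6.9 of them with E2 and 19.9% ± 7.5 with vehicle (SD, n = 6 each). The difference of 25.3 points had an exact permutation p = 0.005, the smallest that 400 arrangements can give. Over all regions the same libraries called 61.8% with E2 and 55.7% with vehicle. Regions chosen by the 19 other ways to set 3 wild-type libraries against 3 were also called more often with E2 in the S118A lines, by 5.13 to 18.5 points (median 10.9), in a comparison added after the data were seen. The 25.3 points exceed each of these. In reverse, of the regions gained in the S118A lines, wild-type libraries called 68.4% ± 6.2 with E2 and 51.7% ± 17.8 with vehicle (SD, n = 3 each; exact p = 0.1, the smallest possible).

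The order of the 11437 regions called by all libraries was compared next, an analysis added after the data were seen. Within each library the regions were ranked by peak score, so a shift describes order within the set, not an amount of GRHL2 bound. With E2, 52 regions rose and 6 fell in rank (limma, adjusted p of at most 0.05), and the 52 had a positive E2 shift in each of the 3 lines. The 52 were chosen by the mean shift of these lines, which favours that sign, so it is no separate evidence of agreement. The region near LAPTM4A (chromosome 2, 20071460 to 20072465) rose from rank percentile 37.6 ± 10.1 to 72.1 ± 6.4 (SD, n = 9 each; limma adjusted p = 4.88e-06). A region near NHERF1, a scaffold protein of the estrogen-induced list, rose from 5.77 ± 3.80 to 41.4 ± 9.8 (chromosome 17, 74769690 to 74770304). Its nearest gene is NAT9. A region near RERG, a growth inhibitor named for its regulation by estrogen, rose from 9.35 ± 8.42 to 42.4 ± 11.9 (chromosome 12, 15243076 to 15243717). Regions inside POC1B, FAM178B, TMEM229B, TPD52L1, FRY, CCDC88C, TRAF3IP2, AMZ1, TMCC1 and ACSS1 and near YEATS4 and TM4SF4 also rose. Regions inside AP5Z1, SPATA17, WIPF1 and ABCC4 fell, but these calls were lost in 7, 14, 13 and 14 of the 18 fits that left out 1 library. Each line alone gave 17 risen regions in wild type, 9 in S118A line 1 and 4 in S118A line 2, with 0, 1 and 0 fallen.

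The estrogen-induced list rose in rank with E2 relative to the other regions (camera adjusted p = 0.00365 with an estimated correlation, limma). Of its 56 regions called by all libraries, 4 rose and 0 fell, and 8 rose and 1 fell when adjusted over the list alone. The 4 lay near RERG, NHERF1, TPD52L1 and EGR3. The region near the transcription factor EGR3 lies inside PEBP4 and rose from percentile 72.7 ± 12.5 to 84.5 ± 6.7 (SD, n = 9 each). No other list passed, and the immediate-early list had an adjusted p = 0.242 with an estimated correlation.

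The 17 regions that rose in wild type had a mean shift of 0.95 normal scores there and of 0.64 in the S118A lines. The exact permutation p = 0.005, the smallest possible, is for E2 against vehicle within the S118A lines. It does not compare 0.64 with 0.95, and choosing the regions in wild type favours the 0.95. No region differed in E2 response between S118A and wild type (limma, smallest adjusted p = 0.586), and at an unadjusted p of at most 0.05 the counts were 231 and 224. Over the 52 risen regions together, the mean percentile went from 48.0 ± 1.2 to 69.5 ± 0.9 in wild type (SD, n = 3 each). It went from 43.9 ± 1.6 to 61.3 ± 2.1 in S118A line 1 and from 44.6 ± 0.7 to 62.0 ± 0.7 in S118A line 2. The S118A shift minus the wild-type shift was -0.14 ± 0.05 normal scores (SE; 95% confidence interval in limma, -0.25 to -0.03). Wild type had a part in choosing these regions, with the same weight as each S118A line. An exact permutation of line labels within treatment gave p = 0.230.

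**Figure D3:**
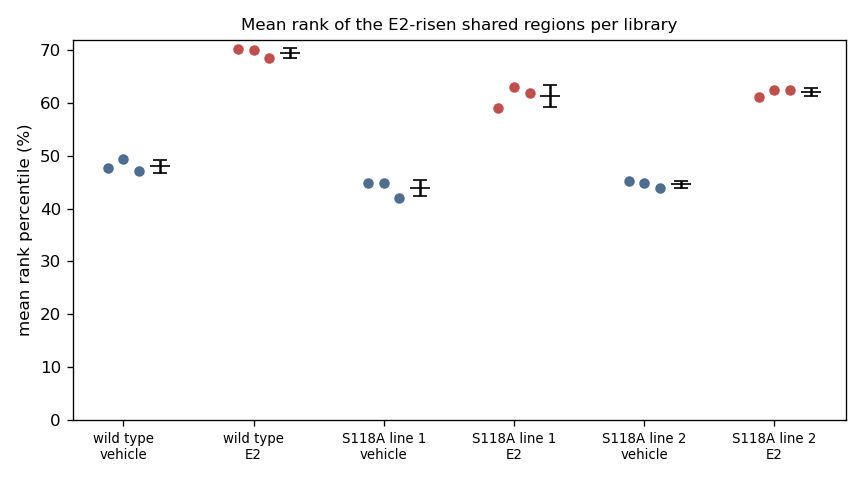
Mean rank percentile of the 52 regions that rose in rank with E2 (y axis, percent) for each library in the 6 groups (x axis). Dots are libraries and bars are the mean ± SD (n = 3); the regions were chosen in these libraries, and the mean reached 69.5 in wild type with E2 and 61.3 and 62.0 in the S118A lines.

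The S118A comparison asks how GRHL2 binding differs between the S118A lines and wild type. Fewer GRHL2 regions were called near ESR1, PGR and the estrogen-induced genes in the S118A lines. Wild-type libraries called 9.5 ± 1.4 (SD, n = 6) of the 16 regions near ESR1 and S118A libraries 5.08 ± 2.50 (SD, n = 12). For PGR, the progesterone receptor gene, they called 3.5 ± 0.55 and 2.0 ± 0 of 6 regions. Of the 164 regions near estrogen-induced genes, wild-type libraries called 66.0% ± 7.9 (SD, n = 6) and S118A libraries 56.7% ± 6.5 (SD, n = 12).

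In exact permutation tests within treatment, ESR1 had p = 0.00198 and PGR p = 0.000142, with adjusted p of 0.0198 and 0.00283 over 20 tests. With 2 S118A lines and 1 wild-type line, the p-values of the S118A comparisons measure the spread between libraries, not between lines. They cannot tell S118A apart from other differences between the lines. S118A line 1 called 7 ± 2.19 regions near ESR1 (exact p = 0.02 against wild type) and S118A line 2 called 3.17 ± 0.41 (exact p = 0.005; SD, n = 6 each). With equal list lengths the ESR1 difference was -2.25 regions (exact p = 0.0111), and that of S118A line 1 alone was -1.17 (exact p = 0.21). TFF1 had 2.33 regions in wild type and 1.58 in S118A, and CLDN4 had 8.33 and 7.42, with adjusted exact permutation p of 0.123 and 0.162. GREB1 had 6.33 and 5.25, XBP1 2.67 and 2.5, FOXA1 1.5 and 1.42, GATA3 2.67 and 3.5, GRHL2 7.33 and 7.42, and CDH1 5 and 5.17. None of these passed.

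The estrogen-induced list differed by -9.30 points (exact permutation p = 0.00213, adjusted p = 0.021), and by -6.09 points beyond all regions (adjusted exact permutation p = 0.0208). The immediate-early list stood at 54.3% in S118A and 62.0% in wild type (adjusted exact permutation p = 0.0639). The luminal list stood at 63.8% and 68.8%, the epithelial list at 64.2% and 67.8%, and the estrogen-repressed list at 75.2% and 80.0%. The mesenchymal list stood at 55.9% and 59.7% and the list of other cell types at 53.1% and 58.5%. The adjusted exact permutation p of these 5 lists ran from 0.110 to 0.403. Peak numbers differed by -1030 between S118A and wild type (exact permutation p = 0.189). S118A line 1 differed from wild type by -2106 peaks (exact p = 0.04), and S118A line 2 differed by 45.8 (exact p = 0.92).

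No region passed the adjusted threshold for S118A in the exact stratified test (smallest adjusted p = 0.0913). At an unadjusted p of at most 0.05, 179 regions were called more often and 668 less often in S118A, and with equal list lengths 250 and 374. Without wild-type E2 replicate 2 the counts were 119 and 618, and no other single library moved either count by over 1.5 times. The smallest p occurred in 17 regions called by 6 of 6 wild-type and 0 of 12 S118A libraries. Those 17 regions passed when the test was limited to regions called by 6 to 12 libraries. They included regions inside SPATA2 (chromosome 20, 49907996 to 49908568), VPS51, MOB3B, CEP83, CDC42EP4, UBXN7, NAB2, UPK1A and LOC124900275 and near QRICH2; NAB2 is a corepressor of EGR factors. Regions called more often in S118A, which missed the threshold, were led by those inside ACAA1 and SDC1, each called by 11 of 12 S118A and 0 of 6 wild-type libraries (adjusted p = 0.168). Regions inside CCSER1, SLC13A1, STX3, ITGA3, UBQLN4, IFT88, RETREG1, SEMA3B and KPNA7 and near GSTK1, XPR1, DR1 and SGO2 followed. SDC1 is the cell-surface proteoglycan syndecan, and ITGA3 is an integrin. Each S118A line alone against wild type gave 0 regions past the adjusted threshold. At an unadjusted p of at most 0.05, 55 were higher and 320 lower in line 1, and 137 and 142 in line 2. The smallest p of this exact test was 0.005, over 8029 regions in line 1 and 7857 in line 2. It passes the adjustment only if more regions reach it than these counts hold, so the 0 does not show a lack of change.

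By rank, 813 regions were higher and 836 lower in S118A than in wild type (limma, adjusted p of at most 0.05). These counts did not require both S118A lines on the same side of wild type, which held for 791 and 815 of them. The region inside ESR1 (chromosome 6, 151702912 to 151703892) was at percentile 91.0 ± 2.7 in wild type, 76.9 ± 3.8 in S118A line 1 and 35.3 ± 9.2 in S118A line 2 (SD, n = 6 each; limma adjusted p = 1.4e-05). A region near FZD10, a Wnt receptor, was at 49.1 ± 5.0 in wild type and 13.7 ± 6.2 in S118A, and regions inside C6orf132, TNK2 and RXRA and near SULF2, RNF208, KRT80, MDH2 and PFDN4 were also lower. The region inside RXRA, a nuclear receptor gene, was at 73.5 ± 3.5 and 47.8 ± 7.7. The regions near MDH2, inside TNK2, and inside RXRA and near RNF208 lie in 10 Mb stretches where 24 of 45, 21 of 48 and 22 of 60 regions were lower and 0 higher. A region near PCDH19, an adhesion molecule, was higher, at 37.4 ± 10.7 in S118A and 3.55 ± 3.46 in wild type. Regions inside NCAM2, ELL, KCTD3, CEP57L1, COL8A1, MARCHF10, KRT8, ZBBX, IQSEC1 and ATXN7 and near TEX55, CTDP1, SLC13A1 and DDB2 were also higher. The S118A lines differed from each other in 1102 regions, 480 higher and 622 lower in line 1.

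Within the fixed lists, 8 regions of the estrogen-induced list were lower and 2 higher in S118A (adjusted over the list alone, 11 and 2). The lower ones lay near CCND1, PGR, RERG, HSPB8, MAPT and EGR3, with 2 regions each near CCND1 and PGR, and the higher ones near P2RY2 and NHERF1. The CCND1 and PGR regions shifted further in line 2. In lines 1 and 2 the shifts were -0.04 and -0.38 for 1 CCND1 region and -0.12 and -0.83 for 1 PGR region. Those near RERG, MAPT and EGR3 shifted further in line 1, and that near HSPB8 shifted by nearly the same amount, -0.75 and -0.72. Between the S118A lines, 7 regions of the list were higher and 0 lower in line 1 (limma). A region that overlaps PGR was at percentile 44.98 ± 8.3 in wild type (SD, n = 6) and 17.6 ± 12.99 in S118A (SD, n = 12). As a set the list had an adjusted p = 0.141 with an estimated correlation. Of the immediate-early list 4 regions were lower, near ZFP36 (2 regions), DUSP1 and EGR3, and 0 higher (adjusted p = 0.186 with an estimated correlation). The epithelial list had 8 lower regions, near CGN, F11R, OVOL1, OVOL2, CLDN3, CLDN4 and ESRP1. It had 2 higher, 1 near RAB25 and 1 near KRT8 and KRT18 (camera adjusted p = 0.682 with an estimated correlation). The regions near CGN and RAB25 lie inside TUFT1 and LMNA. The 3 regions near CLDN3 and CLDN4, with shifts of -0.31, -0.25 and -0.26, lie between 70 and 80 Mb of chromosome 7. There 24 of 45 regions were lower and 0 higher, with a median shift of -0.26, so these 3 did not stand out from their surroundings. The luminal list had 6 lower, near ELF3, GRHL1, NCOA3, SPDEF and ESR1, and 4 higher, near PBX1 and NCOA2 (adjusted p = 0.95 with an estimated correlation).

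**Figure D4:**
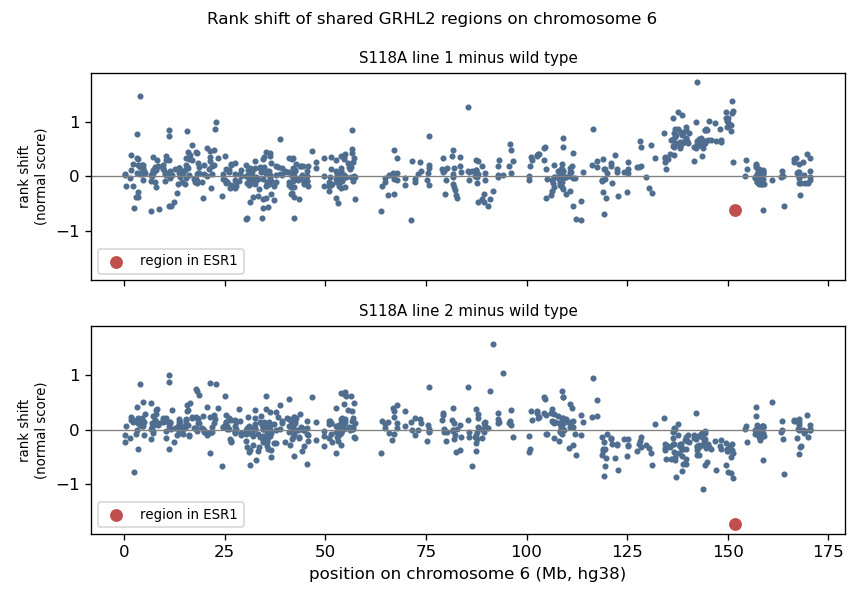
Rank shift of each GRHL2 region called by all libraries along chromosome 6 (x axis, position in Mb on hg38; y axis, shift against wild type in normal scores) for S118A line 1 (top) and S118A line 2 (bottom). Each dot is a region and the large dot is the region in ESR1, with shifts of -0.61 and -1.74; the 18 regions in the 5 Mb before ESR1 have median shifts of 0.97 in line 1 and -0.39 in line 2.

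Line against line, 86 regions were called by 6 of 6 libraries of wild type or S118A line 1 and 0 of 6 of the other. Wild type and S118A line 2 were separated by 62 regions, and the S118A lines were separated from each other by 96.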

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

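The tests of segments along chromosomes, of differences between lines and of list length at ESR1 were chosen only after the results were seen.

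S118A and wild type differed in the rank of 1649 regions, and the S118A lines differed from each other in 1102 regions, a difference between groups. Segments of 50 or more neighbouring regions that shift together do not account for the whole pattern; shorter segments were not tested. Neighbouring regions moved together (correlation 0.220, against at most 0.0185 in 100 shuffles across regions), yet 827 of the calls were called again after the median of 50 neighbours was subtracted in each library. Differences between separately grown lines that have nothing to do with S118A stay open, since the 1102 regions between the S118A lines stand against 1649 between S118A and wild type. An effect of S118A itself stays open as well, with 1 wild-type line in the design.

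At ESR1, fewer regions were called and the region called by all libraries ranked lower in S118A. Shorter S118A lists are not the whole cause (exact permutation p = 0.0111 with equal list lengths). A segment that covers both flanks is not either: in S118A line 1 the 26 regions within 5 Mb had a median shift of 0.85, against -0.61 at ESR1. A difference of 1 line alone is argued against by the exact permutation p = 0.02 of line 1, but with equal list lengths line 1 had an exact permutation p of 0.21. The regions in the 5 Mb before ESR1 had median shifts of 0.97 in line 1 and -0.39 in line 2. In the 5 Mb after it they were 0.15 and -0.0025. The run before ESR1 was longer than 5 Mb. Between 130 and 140 Mb of chromosome 6 the medians were 0.63 in line 1 and -0.31 in line 2. Between 140 and 150 Mb they were 0.66 and -0.29. As ESR1 is the edited gene, a rearrangement that ends at the edited site may contribute. This was not tested, nor was an effect of S118A itself.

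Over the 52 regions that rose with E2, the response of S118A minus that of wild type was -0.14, a difference between groups by its limma interval. The scale of the ranks is argued against, since the difference was -4.08 ± 1.32 percentage points of rank (SE). Over 17 regions chosen in the S118A lines alone the difference was -0.0188 ± 0.0626 (SE), which has no clear sign. These 17 were chosen for their rise in S118A, which favours S118A in the difference. This comparison therefore cannot decide whether the choice of the 52 regions matters. Differences between libraries and lines of this size are an open explanation, since 23.04% of the arrangements of line labels gave a difference as large. That test also counts standing differences between lines.

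S118A line 1 and S118A line 2 differed by -2152 peaks (exact permutation p = 0.01), a difference between groups.

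Other splits of the samples were counted beside the results above. The rule for reading them was set after the results were seen, except for rank counts within a line or between 2 lines. By rank, E2 gave 65 regions in a fit with line and treatment alone and the highest other split 1, and S118A gave 1223 against 5. For each, 1 of 100 splits, the real one, reached the count. For E2 chance can be excluded. For S118A the other splits mix libraries of different lines. They show only that libraries of a line resemble each other, and cannot exclude differences between lines that arose by chance. The same share, 1 of 100, held for wild type against S118A line 1 (1433 against 5), wild type against S118A line 2 (1507 against 3) and the S118A lines (902 against 4). Setting each line against the other two gave 1223 regions for wild type, 1002 for S118A line 1 and 858 for S118A line 2. For calls at an unadjusted p of at most 0.05, E2 gave 263 regions (1 of 100). That is more than in any other split drawn, with a median of 82 in the others. With equal list length E2 gave 104 higher and 49 lower regions, and no other splits were counted at that length. The splits therefore cannot exclude a chance difference in list length as a source of the 263. With the lists as deposited, S118A gave 847 against 824 (1 of 100), a small margin, and the same limit of mixed lines holds. The counts of regions that separate the lines were 86 against 17, 62 against 8 and 96 against 14 (each 1 of 100). These splits also mix libraries of the lines compared. They cannot exclude differences between lines that arose by chance. At the adjusted threshold the E2, S118A and response-difference counts were 0, which every split reaches, so the splits are no test of chance there; the highest counts in other splits were 0, 0 and 1. Within a line 10 splits are too few. The gained and lost regions were 226 against 227 in wild type (2 of 10), 308 against 354 in line 1 (2 of 10) and 259 against 241 in line 2 (1 of 10). The rank counts within a line were 17 against 2, 10 against 3 and 4 against 2 (1 of 10 each).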

How the results depend on the processing

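The alternatives to the rank results were chosen after seeing the data. Of 3495 values under alternatives, 3273 kept their direction and their side of the threshold, over 158 results. Unknown depth limits what a missing call means. The motif alternatives were not run. Where a value below changed, the cause was not tested, except where fewer libraries or regions in the test show it.

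Leaving out each library in turn gave 1131 to 1794 more peaks with E2 and a response difference of 544 to 2368 peaks, -1562 to -650 for S118A, and 0 to 0 changed regions for E2, S118A and the response difference by rank. Fewer libraries raised the per-line counts: wild type gained 212 to 412 and lost 130 to 332, S118A line 1 gained 407 to 768 and lost 45 to 115, and S118A line 2 gained 358 to 527 and lost 73 to 151. Regions that separate the lines numbered 96 to 135 (wild type and line 1), 72 to 94 (wild type and line 2) and 105 to 146 (lines 1 and 2). Gained regions gave 17.96 to 27.2 points in S118A and 6.42 to 22.6 in wild type. The estrogen-induced list gave 8.68 to 11.04 points with E2 and a response difference of -4.42 to 2.06, reversed without wild-type E2 replicate 1 (0.106) and vehicle replicate 3 (2.06). By rank, E2 gave 39 to 71 regions, S118A 1151 to 1642, the shift of the wild-type regions in S118A 0.52 to 0.68, and the response over the 52 regions -0.22 to -0.09.

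With at least 2 of 3 libraries the gained and lost regions were 751 and 510 (wild type), 1241 and 214 (line 1) and 992 and 287 (line 2). With equal list length the gained regions were 96, 100 and 77 and the lost regions of line 1 were 96. Without the weakest 25% of each list the lost regions were 35, 15 and 13. At an unadjusted p of at most 0.05, E2 gave 246 higher and 17 lower regions, against 212 and 4 without the weakest 25% and 172 and 10 among regions called by 6 to 12 libraries; S118A gave 179 and 668, against 111 and 519 and 117 and 352. S118A gave 17 regions past the threshold with a filter of 6 to 12 libraries, where fewer regions were tested, and 17 by Fisher's test without strata. Limma with trend and robust gave 103 E2 regions, and subtracting 50 neighbours gave 1038 S118A regions. The preset correlation gave 2 list calls, the added one being the immediate-early list in S118A (adjusted p = 0.0395).

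Same-numbered libraries of a line correlated by 0.0405 to 0.153 after removal of group means, with 3 of 9 pairs over 0.1, so the numbers do not pair them by the rule set. For all 9 E2 libraries the closest vehicle library nonetheless had the same number. With a replicate block the response over the 52 regions was -0.15 and no longer past limma's threshold, with fewer degrees of freedom, and the rank counts were 39 for E2 and 1478 for S118A. The counts of regions called more and less often with E2 at an unadjusted p of at most 0.05 were 110 and 5.

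Reversed values, none past the adjusted threshold in the reported setting: with equal list length, E2 differences of -0.494 (estrogen-repressed), -0.391 (luminal), -3.56 (mesenchymal) and -0.654 (other cell types) points, a response difference of -2.96 (estrogen-repressed) and an S118A difference of 0.921 (epithelial); with 1 library left out, response differences ran from -2.73 to 6.36 (estrogen-repressed), -0.980 to 4.02 (luminal) and -5 to 4.84 (mesenchymal). For called regions near genes, TFF1 (-0.222) and XBP1 (-0.333) with E2, and GATA3 (-0.167) and CDH1 (-0.0833) in S118A, reversed without the weakest 25%. TFF1 (-0.222) and XBP1 (-0.556) with E2 reversed with equal list length. With 1 library left out the S118A difference ran from -0.25 to 0.0833 for FOXA1 and from -0.0833 to 0.633 for GRHL2.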

Other observations

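The tests in this part were all chosen after the data were seen. The median E2 shifts of the chromosomes followed gene density, but other groupings of the libraries gave relations as strong. Chromosomes 19, 16 and 22 had the highest median E2 shifts of regions called by all libraries, 0.02 each, and X the lowest, -0.03, followed by 4 and 5, each -0.02. Over the 23 chromosomes the median E2 shift had, with the number of protein-coding genes per Mb, Pearson's r = 0.726 (permutation p = 2e-05) and Spearman's rho = 0.819 (permutation p = 1e-05, the smallest that 100000 permutations can give), both with an adjusted p of 8e-05 over 8 relations. Without the 2 chromosomes farthest from the median density r was 0.783. For S118A against wild type r was -0.419 (permutation p = 0.0396, adjusted 0.0634) and rho -0.400 (permutation p = 0.0581, adjusted 0.0775), and r was -0.320 without those 2 chromosomes. Chromosomes of 1 set of cell lines are not independent samples, so these p-values do not test E2. With the E2 labels exchanged among libraries within lines, r = 0.726 had an exact permutation p = 0.0968. The slope on gene density within each library was 0.00196 normal scores per gene per Mb higher with E2 (exact permutation p = 0.117). In S118A against wild type the slope differed by -0.00545 (exact permutation p = 0.00142), with line and S118A not separable.

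Across regions, the E2 shifts of the lines correlated weakly: r was 0.160 between wild type and S118A line 1, 0.148 between wild type and S118A line 2 and 0.151 between the S118A lines. Regions are not independent replicates.

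By the gene lists, 2 regions near CD19, a B cell marker of the list of other cell types, were lower in S118A by rank and 1 region near NEUROD1 was higher. The CD19 regions lie inside ATP2A1 and RABEP2, and the nearest gene of the NEUROD1 region is CERKL. The region near VIM, of the mesenchymal list, and that near IL1R1, of the estrogen-repressed list, were lower, and the VIM region lies inside TRDMT1. No list of these had an adjusted p under the threshold as a set, with 0.682 for other cell types, 0.936 for the mesenchymal list and 0.718 for the estrogen-repressed list with an estimated correlation.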
